A study of Homo sapiens with 8 samples.

How the data were processed

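The cells were HEK293T, either WT or Pcif1-KO, and per the labels' protocols they were transfected with 5 pmol siRNA and harvested 48 h later, when nuclei were isolated and nuclear RNA was purified. Libraries were made with a kit that reads mRNA from its 3′ end, per the labels' protocols, and the series' design text names s4U labelling of nascent RNA. The submitters' processing notes name bcl2fastq 2.20, cutadapt 3.7, STAR 2.7.10a, HTSeq 2.0.1, DESeq2 1.30.1 and the genome build hg38, without saying what each was used for. The authors deposited 2 tables, for long and short genes, each holding the log2 ratio of WT over Pcif1-KO for m6Am and non-m6Am genes with siScram and with siPCF11, which makes 8 columns of ratios. The log2 scale and the direction of the ratio are those given in the titles of the deposited tables, and positive values are higher in WT. How the libraries were scaled, whether the ratios were shrunk, which genes were listed, where the line between long and short genes lies and how m6Am genes were assigned are not given in the sources used here. The tables used here hold no counts, levels, standard errors or p-values, so the depth per sample is unknown and no filter on low values was possible. 3′ end reads also depend on where a transcript is cleaved, so a ratio can reflect a shift in the cleavage site as well as in the amount of RNA.

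Groups were taken from the sample titles. Of the 8 libraries in 7 groups, the ratios rest on WT and Pcif1-KO with siScram and with siPCF11, 1 library each. The PCIF1-WT, EGFP and 2 PCIF1-CD libraries, planned as rescue comparisons, were not analysed here. As each group had 1 library, no test was made within 1 siRNA, and class, list and chromosome values describe these libraries. Genes were not treated as replicates. Over both siRNAs each gene listed in both has 2 ratios, which leave 1 residual degree of freedom if the genotype difference is the same with both. limma was fitted to these 2 ratios for 7591 genes, with moderated two-sided tests of a mean of 0 and p-values adjusted by Benjamini and Hochberg. It found no more variation of spread between genes than chance gives and so used 1 SD, 0.28, for all. A true difference between the siRNAs counts as error in this fit, and the labels name no further WT or Pcif1-KO clone, so the p-values do not cover other clones.

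Of 8801 gene IDs, 8792 had a symbol and 8725 (99.1%) a RefSeq span through that symbol. Coordinates are from RefSeq on GRCh38, the assembly that hg38 names, and are those of the gene. For each length class, for each m6Am class and for each gene list the median over genes was taken, with the middle 50%. The 95% interval of a class median comes from resampling genes 10000 times, and that of a chromosome or list median from 2000 times. It covers the spread over genes, not between cultures. A difference between 2 classes was set beside 10000 random reassignments of genes to classes of the same sizes, or 2000 where genes were reassigned within bins of gene span or within chromosomes. A gene list's median was given as a percentile among 10000 random lists of the same size with the same number of long and short genes. Lists could not be matched on expression. Both treat genes as exchangeable, which genes of a shared pathway or chromosome are not. Windows of 10 Mb were kept where they held at least 15 genes. For window centring the median of the other genes of the window, or of the chromosome where the window held fewer, was taken from each gene. A first version that included the gene itself put 297 values at exactly 0, which pulls class medians to 0, and was replaced. Window centring also removes any true effect that neighbouring genes share.

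Before the data were examined, the long and short class medians, their difference, the gene-by-gene change with siPCF11, 21 gene lists, the alternatives tried and the rule for named genes were fixed. The limma fit over both pairs, the split by m6Am class, the chromosome medians, 6 more gene lists and the alternatives concerning chromosomes, windows and bins of gene span were added after the tables had been seen. The rule names PCIF1, PCF11 and DIS3 where measured, the 5 highest and 5 lowest genes of each length class with siScram among genes with both ratios, and for each list with at least 5 measured genes its highest, its lowest and the gene nearest its median with siScram. TRIB3, the genes beyond 1 with both siRNAs and any members of the 6 added lists were chosen after their values were seen. Lists with under 5 measured genes were given no median.

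The calculation was tested on simulated data made from the real ratios. A shift of 0.05 between m6Am and non-m6Am genes was recovered as 0.050 for the 4516 long genes with siScram, 0.049 for the 5150 long genes with siPCF11, 0.051 for the 3377 short genes with siScram and 0.047 for the 3349 short genes with siPCF11. It fell in the top 2.5% of random reassignments in 98%, 97%, 98% and 81% of 100 simulations, against 3%, 4%, 0% and 1% without a shift. A list of 50 genes shifted by 0.2 was recovered at 0.20 among the 7893 genes with siScram and at 0.20 among the 8499 with siPCF11, and fell in the top 2.5% in 98% and 91% of simulations. For the limma fit, 7591 genes in 2 pairs were simulated 20 times with the fitted spread, 100 genes changed by 0.5 and 100 by 1. These were recovered at 0.51 and 1.00, 21.7% and 94.2% of them were called, and 5.25 unchanged genes were called on average. In all these simulations genes were drawn independently, and the limma errors were drawn from the model that was fitted. They held no shift shared by neighbouring genes, so they cannot show how many false calls regional shifts give. Alternatives were the mean and a mean trimmed by 10% at each end, genes listed in both comparisons, centring on the median of all genes, the longest 50% of long genes against the shortest 50% of short genes, thresholds of 0.5 and 2, random lists without length matching, and, added later, centring by chromosome or window, leaving out chromosomes 11, 20, 21 and X, comparison within 10 bins of gene span and an adjusted p under 0.01. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.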

Results

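Newly made RNA was compared between wild-type (WT) and Pcif1-KO cells of HEK293T, a human embryonic kidney cell line. PCIF1 is the enzyme that writes m6Am, a methylated adenosine next to the mRNA cap. Both genotypes had received either a scrambled siRNA (siScram) or an siRNA against PCF11 (siPCF11), a cleavage and polyadenylation factor that also takes part in ending transcription. Cells were given 5 pmol of siRNA and harvested 48 h later, nascent nuclear RNA was labelled with s4U, a uridine analogue, and mRNA was sequenced from its 3′ end. The labels describe 8 libraries in 7 groups, and the ratios used here rest on 4 of them, 1 per genotype and siRNA. The other 4 libraries, from Pcif1-KO cells given PCIF1-WT, PCIF1-CD or EGFP, were not analysed here. With 1 library per group no test was made within 1 siRNA, and only single genes were tested over the 2 library pairs together. The read depth behind each ratio is unknown.

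The values are log2 ratios of WT over Pcif1-KO, given separately for each siRNA, so that a positive value means a higher value in WT cells. They are read as nascent RNA after the s4U labelling, but whether they count labelled RNA only could not be checked. A shift in the cleavage site could change them as well. A ratio was listed for 7893 genes with siScram, for 8499 with siPCF11 and for 7591 with both. The authors had divided the genes into a long and a short class, and each of these into m6Am and non-m6Am genes. Long genes had a median RefSeq span of 52.4 kb and short genes one of 9.89 kb, but the classes overlap in span. Spans over 20 kb were found for 13% of short and 95.3% of long genes, and the shortest span in the long class was 1.77 kb. PCIF1 itself was not analysed here, so the knockout label has no check from its own target. PCF11 could not serve as a check of its knockdown either, because both libraries of each ratio had received the same siRNA. PCF11 (ENSG00000165494.11, hg38 chromosome 11, 83157131 to 83187451) had log2 ratios of -0.44 with siScram and -0.45 with siPCF11 in the authors' deposited tables, and -0.15 and -0.17 after centring on the median of its chromosome. DIS3, the catalytic subunit of the nuclear exosome, had ratios of -0.48 and -0.97 in the authors' deposited tables. Its 10 Mb window on chromosome 13 had medians of -0.15 with siScram and -0.58 with siPCF11. Relative to the other genes of that window DIS3 was at -0.33 and -0.40.

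The siScram libraries compare nascent RNA between the WT and Pcif1-KO lines when PCF11 is not targeted. With 1 library per genotype, the loss of PCIF1 cannot be separated from other differences between the lines. Genes for the cytosolic ribosome, the mitochondrial respiratory chain, the integrated stress and unfolded protein responses and axon guidance were lower in WT than in Pcif1-KO cells as groups. Genes of the m6Am and m6A methylation machinery were higher, though less clearly so once the shifts of their chromosome regions were removed. Of 78 measured cytosolic ribosomal protein genes, 68 had a ratio below 0, with a median of -0.31 (middle 50% of genes -0.44 to -0.11). Of 74 nuclear-encoded respiratory chain genes, 56 were below 0, with a median of -0.25 (-0.42 to -0.01). In the stress list 23 of 25 genes were below 0 (median -0.35, middle 50% -0.61 to -0.21), and in the axon guidance list 10 of 12 (median -0.37, middle 50% -0.71 to -0.17).

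The authors' deposited tables gave RPL23 the lowest siScram ratio among ribosomal protein genes, at -1.16, with RPS15A near the middle at -0.31 and RPS21, on chromosome 20, highest at 0.41. Within the respiratory chain, the complex III subunit UQCRC1 was at -1.24, UQCRH at -0.25 and the succinate dehydrogenase subunit SDHB at 0.68 in the authors' deposited tables. CHAC1, a glutathione-degrading enzyme induced by ATF4, was lowest of the stress genes at -1.18 and HERPUD1, a component of endoplasmic reticulum protein degradation, was nearest their median at -0.35, per the authors' deposited tables. Only CEBPB and TRIB3 of the stress genes were above 0, at 0.20 and 0.16 in the authors' deposited tables, and both lie on chromosome 20, which stood above 0 as a whole. The axon guidance cue NTN1 was at -0.97, its list's ephrin ligand EFNA5 at -0.40 and a further ephrin ligand, EFNB2, at 0.83 in the authors' deposited tables.

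In the methylation list 11 of 17 genes were above 0, with a median of 0.26 (middle 50% -0.08 to 0.41). WTAP, a subunit of the m6A writer complex, was highest at 0.72, the m6A demethylase ALKBH5 was nearest the median at 0.26, and YTHDC1, a nuclear m6A reader, was lowest at -0.40 in the authors' deposited tables. Each of these 5 lists lay outside the middle 95% of 10000 random lists of the same size and length-class makeup. The ribosomal protein and respiratory chain medians were below every random list, the stress and axon guidance medians were at percentiles 0.010 and 0.070, and the methylation median was at percentile 99.8. These 5 were the only lists so placed among the 19 with at least 5 genes measured with siScram.

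The remaining lists had siScram medians between -0.10 and 0.15. Proteasome subunits had a median of -0.10 (percentile 12.2), from PSMC3 at -0.91 to PSMA7 at 0.51 in the authors' deposited tables. Nuclear exosome genes had a median of 0.15 (percentile 95.8), with MPHOSPH6 at 0.78 in the authors' deposited tables. Cleavage and polyadenylation factors had a median of 0.05 (percentile 75.4), and ranged in the authors' deposited tables from RBBP6 at -0.73 to CSTF1, on chromosome 20, at 1.09. Medians were 0.10 for p53 targets and for core histones (percentiles 90.3 and 89.7), 0.07 for the U1 snRNP and spliceosome core (87.7), 0.06 for immediate early genes (85.5), 0.03 for transcription elongation factors (69.3) and 0.01 for Integrator subunits (57.7). Genes of homologous recombination and Fanconi repair had a median of 0.01 (percentile 55.6) and mitotic genes one of 0.00074 (56.7). Mitochondrial ribosomal proteins had a median of -0.07 (percentile 17.3), cholesterol synthesis genes -0.04 (36.3) and zinc finger genes named ZNF -0.03 (23.7). For Integrator subunits and for the repair genes the mean was below 0, at -0.03 for each, although the median was above it. Interferon-stimulated genes had 3 measured members, all below 0, and none of the markers of other lineages had a listed ratio.

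**Figure D1:**
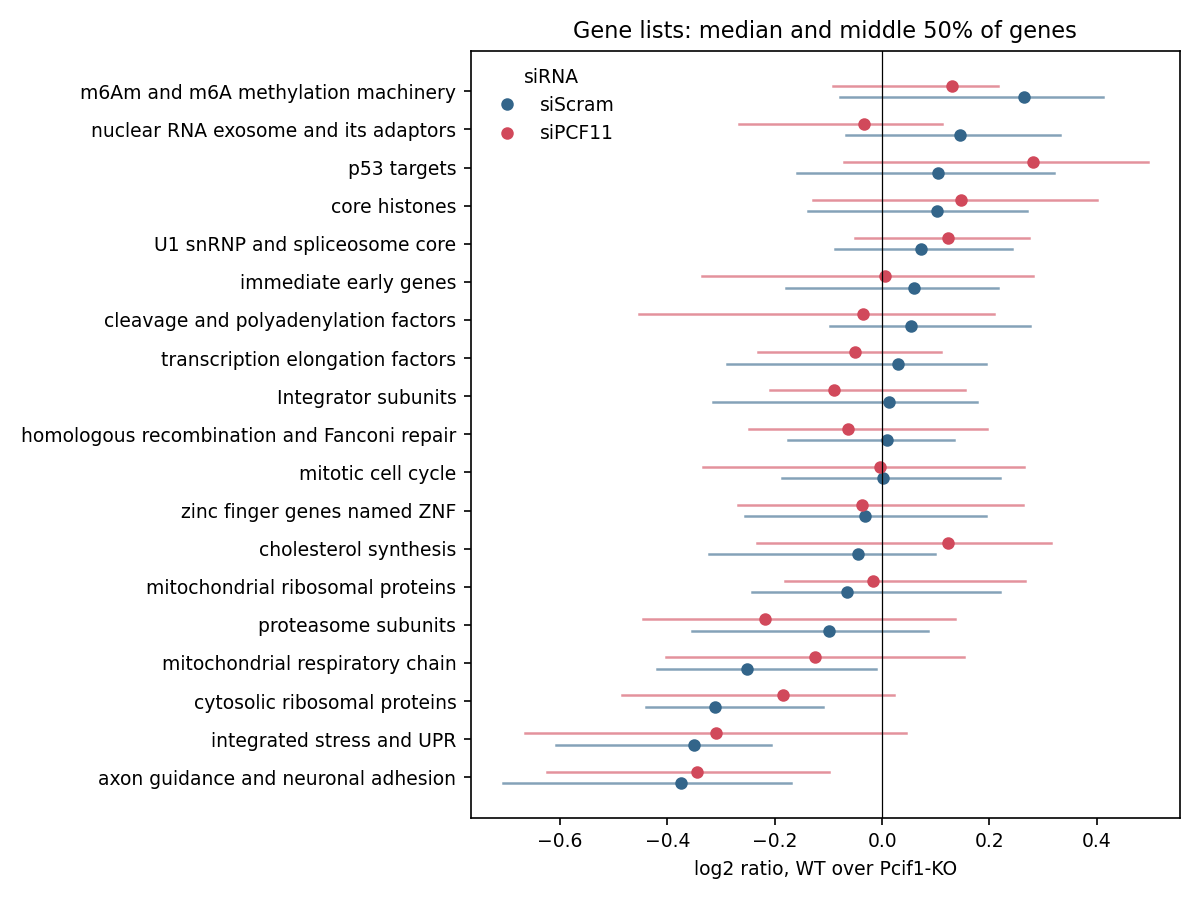
Median log2 ratio of WT over Pcif1-KO (points) and middle 50% of genes (lines) for the gene lists with at least 5 genes measured with siScram, in the siScram and siPCF11 comparisons, each from 1 library per genotype. Ribosomal protein, respiratory chain, stress response and axon guidance genes have medians below 0 with both siRNAs.

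Single genes differed by more than the groups did. With siScram, 31 genes had a log2 ratio above 1 and 41 one below -1. NEFM (ENSG00000104722.13, hg38 chromosome 8, 24913761 to 24919093), the medium neurofilament chain, was lowest at -2.71 in the authors' deposited tables, which is 6.56-fold higher in Pcif1-KO cells. The transcriptional co-regulator CITED1 followed at -2.23, and the X-linked MAGE family genes MAGEA1 and MAGEH1 were both at -1.74 in the authors' deposited tables. HYOU1, a chaperone of the endoplasmic reticulum on chromosome 11, completed the 5 lowest short genes at -1.40 in the authors' deposited tables. Among long genes the transcription factors GATA3 (hg38 chromosome 10, 8045333 to 8075198) and GATA6 (chromosome 18, 22169589 to 22202528) were at -1.63 and -1.26 in the authors' deposited tables. The protocadherin PCDH7 was at -1.21 in the authors' deposited tables, where the 2 chromosome 11 genes MRPL23 and CFL1, which encodes the actin-binding cofilin, were at -1.14 and -1.12. CFL1 was in the authors' long class, although its RefSeq span was 3.51 kb.

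At the other end, the transcription factor RUNX3 (ENSG00000020633.18, hg38 chromosome 1, 24899511 to 24965138) had the highest ratio of the long genes, 2.28 in the authors' deposited tables, or 4.85-fold more in WT cells. TSC22D3, a glucocorticoid-induced gene, was at 1.82, the kinase gene STK35 at 1.28, FOXRED2 at 1.25 and the nuclear receptor coactivator NCOA5 at 1.17 in the authors' deposited tables. STK35 and NCOA5 lie on chromosome 20. The highest short genes in the authors' deposited tables were the keratin-associated KRTAP19-1 at 2.26, the ribonuclease P subunit RPP25 at 1.51, the homeobox gene UNCX at 1.44, LRATD2 at 1.42 and the p53 target PHLDA3 at 1.40.

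By length class, the siScram medians lay within 0.03 of 0. Long genes had a median of 0.0031 (95% of gene resamplings -0.0077 to 0.012) and short genes one of -0.027 (-0.040 to -0.016). The long minus short difference of 0.030 was reached or passed in 5 of 10000 random reassignments of genes to classes of the same sizes. It was 0.015 after each gene was centred on the median of its chromosome and 0.018 without chromosomes 11, 20, 21 and X, which 238 and 244 of 10000 random reassignments reached. Centred on the other genes of the same 10 Mb window it was 0.012, which 975 of 10000 reached, so it is not set apart from regional shifts. Within m6Am genes it was 0.049 (1 of 10000), and 0.033 (40 of 10000) after window centring, but within non-m6Am genes it was 0.020 (932 of 10000), and -0.0011 (5433 of 10000) after chromosome centring. Over 10 bins of RefSeq gene span the siScram median of m6Am genes did not rise steadily with span. It was -0.14 in the shortest bin, highest at 0.056 in bin 6 and -0.069 in the longest. Non-m6Am genes were at -0.039 in the shortest bin, 0.056 in bin 6 and -0.10 in the longest. The m6Am genes thus lay lower in the shortest bin, level in bin 6 and higher in the longest. Long m6Am genes had a median of 0.023 and long non-m6Am genes one of -0.0095, a difference of 0.032 (0.011 to 0.062) that 18 of 10000 random reassignments reached. After window centring the long classes differed by 0.026 (121 of 10000). Short m6Am and short non-m6Am genes had medians of -0.026 and -0.030, and their difference of 0.0035 was reached in 3975 of 10000. The reassignments describe genes within these libraries and say nothing of other cultures. Centred on the median of all genes (-0.0096), the long-gene median was 0.013 and not 0.0031.

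**Figure D2:**
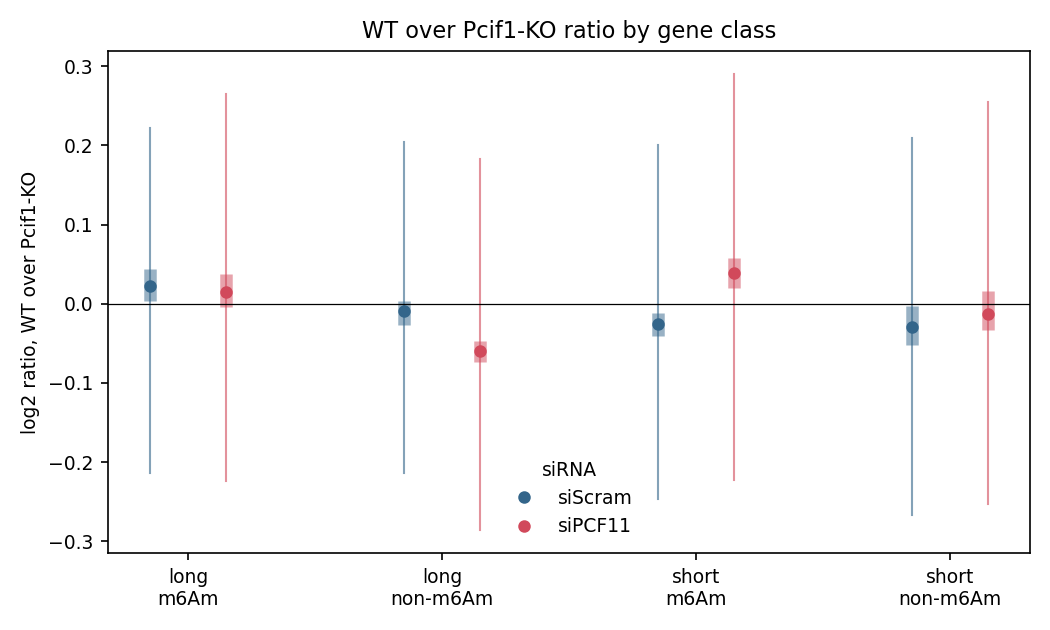
Median log2 ratio of WT over Pcif1-KO (points) in the 4 gene classes with siScram and siPCF11, with 95% of gene resamplings (thick bars) and the middle 50% of genes (thin lines), each from 1 library per genotype. The class medians lie between -0.059 and 0.039.

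The siPCF11 libraries address whether the WT and Pcif1-KO cells still differ in the same way when PCF11 is targeted by siRNA. Ribosomal protein, respiratory chain, stress response and axon guidance genes were again lower in WT cells, and p53 targets were higher. The ribosomal protein median was -0.18 with 57 of 78 genes below 0. With both siRNAs 52 of the 78 genes were below 0, close to what independent lists of these sizes would share. The respiratory chain median was -0.13 (49 of 73 below 0), the stress median -0.31 (17 of 24 below 0) and the axon guidance median -0.34 (14 of 17 below 0). Of 19 p53 targets, 13 were above 0, with a median of 0.28 (middle 50% -0.07 to 0.49).

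Among p53 targets PHLDA3 was at 2.32, the nucleotide excision repair gene XPC at 0.53 and the cell cycle inhibitor CDKN1A at 0.53 in the authors' deposited tables. RPL23 at -1.24, NTN1 at -0.91 and HERPUD1 at -0.71 were below 0 here too in the authors' deposited tables, while CHAC1 and UQCRC1 were nearer 0, at -0.33 and -0.20. The ribosomal protein median lay below every random list, and percentiles were 0.54 for the respiratory chain, 0.040 for the stress list, 0.080 for axon guidance and 99.6 for p53 targets. Proteasome subunits also lay outside the middle 95%, with a median of -0.22 (21 of 32 below 0, percentile 0.30), but at percentile 9.25 once each gene was centred on the median of its chromosome. The methylation list had a median of 0.13 (percentile 90.3), with WTAP at -0.18, ALKBH5 at 0.35 and YTHDC1 at 0.08 in the authors' deposited tables. Whether the methylation and p53 lists differ between the siRNAs was not tested.

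Medians with siPCF11 were 0.15 for core histones (percentile 87.7) and 0.12 both for the U1 snRNP and spliceosome core (93.9) and for cholesterol synthesis genes (88.6). Cleavage and polyadenylation factors had a median of -0.03 (percentile 43.6), with PAPOLA, a poly(A) polymerase, at -0.81 in the authors' deposited tables. Nuclear exosome genes had a median of -0.03 (39.8), transcription elongation factors -0.05 (31.1), repair genes -0.06 (29.7) and Integrator subunits -0.09 (26.8). Medians nearer 0 were found for mitotic genes (-0.0043, percentile 50.2), immediate early genes (0.0052, 44.8), mitochondrial ribosomal proteins (-0.02, 33.2), interferon-stimulated genes (-0.02 over 6 genes, 46.2) and zinc finger genes named ZNF (-0.04, 10.9). The means of Integrator and of interferon-stimulated genes were above 0, at 0.06 and 0.16, and that of immediate early genes was below it, at -0.0075.

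With siPCF11, 71 genes had a log2 ratio above 1 and 56 one below -1. NEFM was at -3.23, which is 9.36-fold higher in Pcif1-KO cells, and CITED1 at -2.98 in the authors' deposited tables. MAGEA1 was at -2.21, MAGEH1 at -1.86, PCDH7 at -1.54, GATA3 at -1.46 and both GATA6 and HYOU1 at -1.14 in the authors' deposited tables. UNCX at 2.13, LRATD2 at 2.11, RPP25 at 1.67, KRTAP19-1 at 1.64 and TSC22D3 at 1.15 were above 1 again in the authors' deposited tables. RUNX3, the highest gene with siScram, was at 0.55, and MRPL23 was at -0.29 in the authors' deposited tables.

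Long genes had a siPCF11 median of -0.030 (95% of gene resamplings -0.042 to -0.015) and short genes one of 0.022 (0.0047 to 0.038). The long minus short difference was -0.053, lower than in every one of 10000 random reassignments. It was -0.031 after chromosome centring and -0.059 without chromosomes 11, 20, 21 and X. After window centring it was -0.013, inside the random range of -0.016 to 0.017. Within m6Am genes it was -0.024 (95% of gene resamplings -0.051 to 0.0058), inside the random range of -0.029 to 0.030, and within non-m6Am genes it was -0.046, where 9991 of 10000 random reassignments lay at or above it, but -0.0071 after window centring, inside the random range of -0.025 to 0.024. Long non-m6Am genes were lowest, with a median of -0.059 and 43.5% of genes above 0, and long m6Am genes were at 0.015, a difference of 0.074 (0.052 to 0.0998) that none of 10000 random reassignments reached. Short m6Am genes had a median of 0.039 and short non-m6Am genes one of -0.013, and 13 of 10000 random reassignments reached their difference of 0.052. After each gene was centred on the median of its chromosome, the difference between the long classes was 0.044 and the median of all long genes -0.011. After window centring the long classes differed by 0.033 (11 of 10000) and the short classes by 0.031 (159 of 10000).

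Set side by side, the ratios with siScram and siPCF11 come from separate libraries of the same WT and Pcif1-KO lines. Genes far from 0 with one siRNA tended to be far from 0 with the other. Of the 31 genes above 1 with siScram, 30 were above 0 with siPCF11, and of the 39 genes below -1 that were listed in both, 36 were below 0. Above 1 in both were 14 genes, where independent lists of these sizes would share 0.286, and below -1 in both were 14, where independent lists would share 0.283. The 14 lower genes comprised NEFM, CITED1, MAGEA1, MAGEH1, GATA3, HYOU1, GATA6, PCDH7 and RPL23 together with ADM, GMPPB, BEX1, ISL1 and RUNX1T1, and 12 of the 14 higher but 6 of the 14 lower genes were in m6Am classes, to which 52.8% of the 7591 genes belonged. Over all 7591 genes Pearson's r was 0.435 and Spearman's rho 0.359, across genes, which are not independent replicates, and 61.7% of genes had the same sign. The gene-by-gene change from siScram to siPCF11 had a median of -0.012 (95% of gene resamplings -0.028 to 0.0025) in long genes and 0.032 (0.016 to 0.052) in short genes, the latter at -0.0035 after window centring.

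Over both library pairs, limma called 417 of 7591 genes at an adjusted p under 0.05, 203 higher and 214 lower in WT. The fit takes the genotype difference to be the same with both siRNAs and covers these WT and Pcif1-KO lines only. The gaps between the 2 ratios, pooled over all genes into 1 SD, serve as error. A call therefore rests on the mean of a gene's 2 ratios, and the gene's own gap plays no part. RUNX3, at 2.28 with siScram and 0.55 with siPCF11, was called. Of the 417 genes 118 lay on chromosomes 11, 20, 21 and X. These chromosomes held 443, 227, 77 and 266 of the 7893 genes listed with siScram, a smaller share than among the called genes. Of the 417 genes, 301 were also called in the same direction after chromosome centring and 233 after window centring. With the sign of the siPCF11 pair flipped, 29 genes passed the smallest mean ratio called, 0.60. All 28 genes beyond 1 in both pairs were called, which had to be so because their means lie past 0.60. Of the called genes 57.8% were in m6Am classes. Called lower were 7 of 78 ribosomal protein genes, 9 of 73 respiratory chain genes and 7 of 24 stress genes, and none of these was called higher. Chromosome centring kept 7, 6 and 7 of these calls, and window centring 5, 4 and 6. In the axon guidance list 2 of 12 were called lower and 1 higher, in the p53 list 2 of 19 were called higher, and in the methylation list YTHDF1, on chromosome 20, was the 1 gene called of 17. The YTHDF1 call was lost after chromosome centring, 1 of the 2 p53 calls after window centring, and the 3 axon guidance calls were kept under both.

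**Figure D3:**
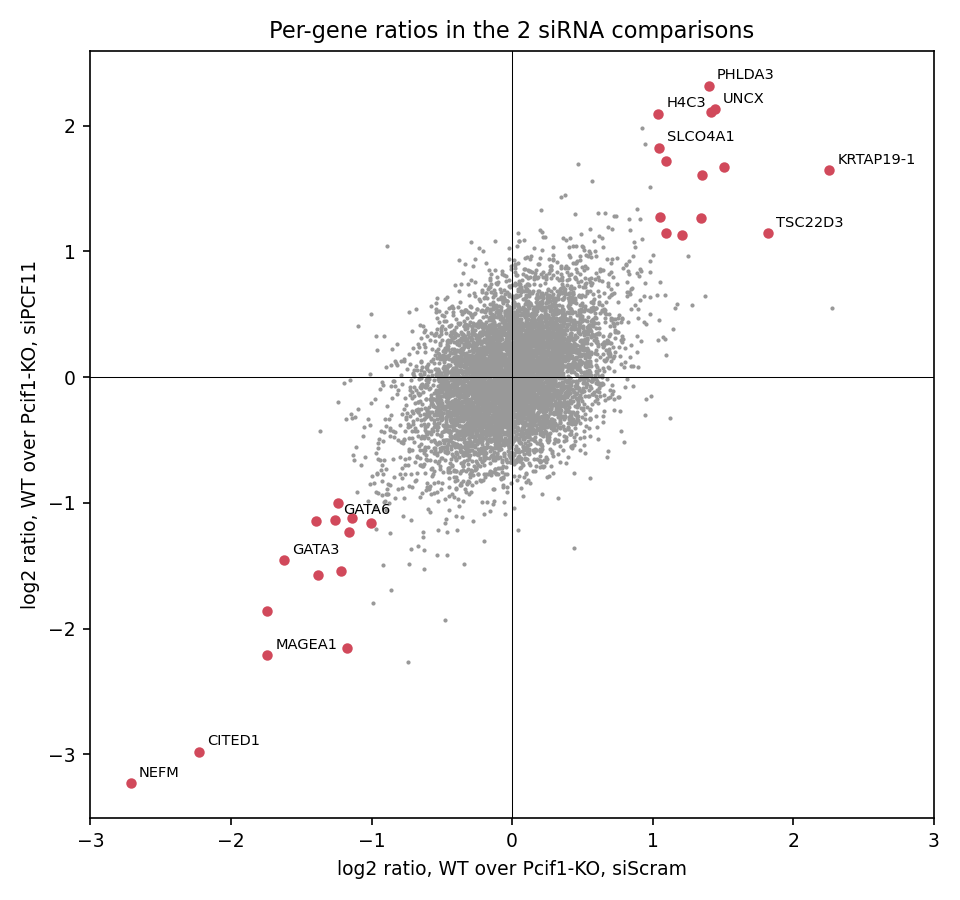
Log2 ratio of WT over Pcif1-KO with siScram (x axis) and siPCF11 (y axis) for 7591 genes listed in both (grey), with the genes beyond 1 in the same direction in both in red. The 14 red genes at lower left, among them NEFM and CITED1, are higher in Pcif1-KO cells, and the 14 at upper right are higher in WT cells.

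Some chromosomes were shifted between the lines with both siRNAs. Genes of chromosome 11 had a median of -0.29 with siScram, where 14.2% of 443 genes were above 0, and -0.27 with siPCF11, where 23.5% of 456 were. Chromosome 20 had medians of 0.29 (82.8% of 227 genes above 0) and 0.37 (85.4% of 247). Chromosome 21 was at 0.19 and 0.15 and the X chromosome at -0.12 and -0.12. Others moved between the siRNAs, such as chromosome 19 from -0.050 to 0.11, chromosome 22 from 0.010 to 0.14, chromosome 16 from -0.020 to 0.085, chromosome 17 from -0.047 to 0.049 and chromosome 6 from 0.0073 to -0.10. Over the medians of the 23 chromosomes, which are not independent replicates, Pearson's r was 0.793 and Spearman's rho 0.504. Along chromosome 11, 9 of 9 windows of 10 Mb with at least 15 genes had medians below 0 with both siRNAs, and along chromosome 20, 6 of 6 had medians above 0. Parts of other chromosomes were shifted as far. Of 17 windows beyond 0.2 in the same direction with both siRNAs 7 lay outside chromosomes 11, 20, 21 and X. These were 3 windows in the first 30 Mb of chromosome 1 (0.25 to 0.28 with siScram, 0.31 to 0.44 with siPCF11), 20 to 40 Mb of chromosome 18 (-0.25 and -0.31, then -0.28 and -0.45), 30 to 40 Mb of chromosome 17 (-0.40 and -0.30) and 120 to 130 Mb of chromosome 12 (-0.23 and -0.22). RUNX3 and SDHB lie in the first of these regions, GATA6 in the second and RPL23 in the third. Relative to their windows, the siScram and siPCF11 values were 2.03 and 0.24 for RUNX3, 0.41 and -0.13 for SDHB, -1.03 and -0.88 for GATA6 and -0.77 and -0.94 for RPL23, from the authors' deposited tables. Genes named from these chromosomes, such as HYOU1, CFL1, MRPL23 and PSMC3 on chromosome 11 and STK35, NCOA5, CSTF1, PSMA7 and RPS21 on chromosome 20, had siScram ratios in their chromosome's direction, whereas the X-linked TSC22D3 went against its own. The ribosomal protein, respiratory chain, stress, axon guidance, methylation and p53 lists kept their place outside the middle 95% after each gene was centred on its chromosome, in the siRNA comparisons in which they had it before. After window centring the methylation list moved inside (percentile 94.2 with siScram) and the other 5 stayed outside. With that centring p53 targets with siScram (99.2) and zinc finger genes named ZNF with siPCF11 (0.19) lay outside as well.

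**Figure D4:**
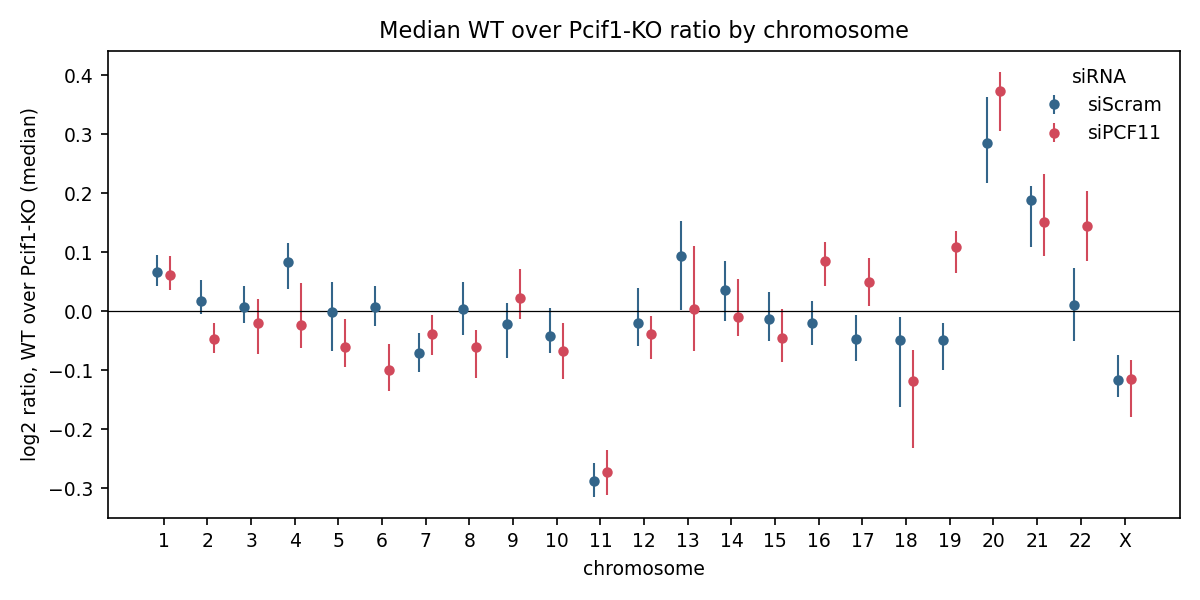
Median log2 ratio of WT over Pcif1-KO per chromosome with siScram and siPCF11, with 95% of gene resamplings (bars), each from 1 library per genotype. Chromosome 11 lies at -0.29 and -0.27 and chromosome 20 at 0.29 and 0.37.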

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

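The test of genes listed in 1 comparison and those with window centring were chosen only after the result was seen, whereas those of gene span and chromosome makeup were set down before their results. Short m6Am genes had a median log2 ratio of -0.026 (95% of gene resamplings -0.041 to -0.011) with siScram and 0.039 (0.020 to 0.058) with siPCF11, a change of 0.065, and of 0.043 (from -0.0089 to 0.034) after chromosome centring. It was picked out because the medians lie on opposite sides of 0, and the difference was not tested across libraries. The long minus short difference went from 0.030 with siScram to -0.053 with siPCF11, a change of -0.083, for the same reason and likewise not tested. After chromosome centring it went from 0.015 to -0.031, a change of -0.046, and after centring on 10 Mb windows from 0.012 to -0.013, both inside the range of random reassignments.

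Of the genes named by rule, 5 were picked out because their ratios lay more than 0.2 from 0 in opposite directions with the 2 siRNAs, and the difference was not tested for any of them. The search covered the named genes only, and 617 of all 7591 genes (8.13%) lay as far apart, so these 5 are examples. MVD, a cholesterol synthesis enzyme, went from -0.74 to 0.52 in the authors' deposited tables, a change of 1.25. CDKN1A, the p53 target that inhibits the cell cycle, went from -0.36 to 0.53 in the authors' deposited tables (change 0.89). SARS1, the cytosolic seryl-tRNA synthetase, went from -0.20 to 0.31 in the authors' deposited tables (change 0.51). BARD1, the partner of BRCA1, went from 0.45 to -0.35 in the authors' deposited tables (change -0.80), and CCNK, the cyclin partner of CDK12, from 0.55 to -0.32 (change -0.87). Over all 7591 genes the SD of the change was 0.40.

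The m6Am minus non-m6Am difference of long genes with siPCF11, 0.074, was weighed against properties in which the classes differ. Restricted to genes listed with both siRNAs it was 0.078, which argues against genes that entered the list with siPCF11 as its source. Within 10 bins of RefSeq gene span it was 0.058, where 2000 random reassignments within bins gave -0.025 to 0.023, and after chromosome centring it was 0.044, where 2000 random reassignments within chromosomes gave -0.022 to 0.023, so neither the shorter span of m6Am genes nor their chromosomes account for all of it, though the chromosome-centred value, and that of 0.033 after window centring (10000 random reassignments -0.021 to 0.020), lie under the interval of the uncentred one (0.052 to 0.0998). With siScram the difference was 0.032. Within bins of gene span it was 0.020 with siScram against 0.058 with siPCF11, and after chromosome centring 0.026 against 0.044. Only after window centring was the siScram difference, 0.026, near the 0.033 with siPCF11. The gene-by-gene change with siPCF11 was higher in long m6Am than in long non-m6Am genes by 0.032 (0.0020 to 0.060), and by 0.017 after window centring. The m6Am difference is therefore not shown to be particular to siPCF11. GC content, expression level and the position of the cleavage site were not tested. A dependence of nascent RNA on m6Am may therefore be kept as a hypothesis beside these, since 1 library per genotype cannot separate it from other differences between the lines.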

How the results depend on the processing

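All alternatives concerning chromosomes, windows, bins of gene span or the limma fit were chosen after the data were seen. Class medians, class differences and gene counts were recomputed in 136 ways, of which 109 left the value inside its interval over genes, or the count within 1.5 times, and 27 moved it. The sign changed in 6 of the 136. The long-gene siScram median went from 0.0031 to -0.0014 as a mean and -0.00075 as a trimmed mean, and the short m6Am minus non-m6Am siScram difference from 0.0035 to -0.0027 in genes listed in both, -0.0080 after chromosome centring and -0.016 after window centring. The change with siPCF11 in short genes went from 0.032 to -0.0035 after window centring. That centring also moved the long-gene siPCF11 median to -0.0069, the short-gene siScram median to -0.0010, the long minus short differences to 0.012 with siScram and -0.013 with siPCF11, the long m6Am minus non-m6Am difference with siPCF11 to 0.033 and the genes above 1 with siPCF11 from 71 to 44. Of 350 alternatives for gene list medians 346 left the value inside the 95% interval from resampling the list's genes, which is wide for short lists. The sign changed in 29 of the 350, over 13 results, of which 28 concerned lists inside the middle 95% of random lists. Examples are elongation factors with siScram (0.03 to -0.04 after chromosome centring), ZNF genes with siPCF11 (-0.04 to 0.02 in genes listed in both) and Integrator subunits with siPCF11 (-0.09 to 0.06 as a mean). Centring on the median of all genes moved the long-gene siScram median from 0.0031 to 0.013, by construction. Centring each gene on its chromosome moved the long-gene siPCF11 median from -0.030 to -0.011, the short-gene siScram median from -0.027 to -0.0078 and the long m6Am minus non-m6Am difference with siPCF11 from 0.074 to 0.044. Without chromosomes 11, 20, 21 and X the short-gene siScram median was -0.011, and 27 genes instead of 41 were below -1 with siScram; the cause was not tested beyond the removal of those genes. At a threshold of 0.5, 482 genes were higher and 551 lower in WT with siScram, and 749 and 739 with siPCF11. At a threshold of 2 these were 2 and 2 with siScram and 4 and 5 with siPCF11. The MAGE, BEX and TCEAL list reversed to 0.23 with siPCF11 and moved to -0.049 with siScram without those chromosomes, because 1 of its genes, MAGEF1, lies elsewhere. No value was exactly 0 or beyond 5 and no symbol was repeated, so those alternatives changed nothing. Alternatives on expression level, on the authors' adjusted p, on counts or pseudocounts and on the rescue libraries were not run. The limma counts over both pairs were 108 higher and 116 lower at an adjusted p under 0.01, 131 and 124 without chromosomes 11, 20, 21 and X, 159 and 169 after chromosome centring, 125 and 131 after window centring and 210 and 196 after centring on the median of all genes, against 203 and 214. Random lists drawn without length matching left 5 lists with siScram and 6 with siPCF11 outside the middle 95%, as with matching. Depth is unknown here, so the error it leaves on single genes could not be given.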

Other observations

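Of the tests below, those of library scaling and the 3 on the listing of long genes were chosen only after the result was seen, and the 6 gene lists of the next paragraph were drawn up after the ratios had been looked at. HOX genes, the homeobox transcription factors of body patterning, had a median above 0 with both siRNAs. With siScram 22 of 31 were above 0 with a median of 0.24, and with siPCF11 the median was 0.22, with 18 genes above 0 with both siRNAs. As these 6 lists were drawn up from the same ratios, no random lists are set beside them. HOXA10 was at 0.86 and 1.07 and HOXB4 at 0.75 and 0.94 in the authors' deposited tables, whereas HOXB6 was at -0.62 and -1.52. Genes of the MAGE, BEX and TCEAL families were lower in WT, 15 of 16 with siScram (median -0.31) and 12 of 16 with siPCF11 (median -0.50), among them BEX1 at -1.17 and -2.15 in the authors' deposited tables. Of these 16 genes 15 are X-linked, and after chromosome centring the medians were -0.19 and -0.38.

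Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, were below 0 in 15 of 20 genes with siScram (median -0.22) but in 9 of 20 with siPCF11 (median 0.02), and that difference was not tested. FARSB was at -0.79 and 0.01 and RARS1 at -0.20 and 0.63 in the authors' deposited tables. Genes of the endoplasmic reticulum translocon and of glycosylation had medians of -0.16 (24 of 33 below 0) and -0.17 (26 of 33), or -0.14 and -0.11 after chromosome centring. Of 5 protocadherins 4 were below 0 with siScram (median -0.37) and 4 of 4 with siPCF11, with PCDH9 at -0.92 and -1.49 in the authors' deposited tables. Glycolysis genes had medians of -0.15 and -0.02, the latter with a mean of 0.0027.

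Chromosomes 11 and 20 stood apart from the rest in opposite directions. The siScram medians of chromosomes 20 and 11 differed by 0.57, which 1 scaling factor per library cannot give, and by 0.57 after each gene class was centred on its own median, so the length and m6Am makeup of these chromosomes does not account for it either. In 16 of 16 combinations of the 2 chromosomes, 4 gene classes and 2 siRNAs the shift had the direction of its chromosome. As the chromosomes were picked for their medians, that count had little room to come out otherwise and decides nothing. A different copy number in the WT and Pcif1-KO lines may shift a chromosome or part of it, but it stays an open hypothesis and cannot be told apart from other causes of regional shifts, as no DNA was used here. If it holds, ratios of genes in the shifted regions mix it with any effect of PCIF1.

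Long genes entered the tables with siPCF11 more often than they left. Of long genes listed with 1 siRNA only, 763 were listed with siPCF11 and 129 with siScram, while for short genes these were 145 and 173, or 45.6% with siPCF11 (exact binomial 95% interval 40.0% to 51.2%), which argues against a greater depth for all genes alike. In 4 of 4 classes the genes that entered had a longer median span than those listed with both, such as 83.5 kb against 60.4 kb for long non-m6Am genes, as a listing that depends on gene span may give. Whether this is an effect of the PCF11 knockdown or of the 1 pair of libraries with siPCF11 cannot be told apart, because a further pair was not analysed here. Lower expression of very long genes was not tested, as no levels were used.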
